A study of Danio rerio with 2 samples.

How the data were processed

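The study immunoprecipitated RNA with a Flag-tagged zebrafish Cpeb1b protein and sequenced it (RNA immunoprecipitation sequencing, RIP-seq). Embryos injected with Flag-cpeb1b mRNA were collected at 16 h post-fertilization (hpf), a mid-somitogenesis stage. Per the labels' protocols, lysates were incubated with anti-FLAG magnetic beads, the RNA that stayed on the beads after washing was fragmented, and libraries were made with a small-RNA kit. The series holds 2 samples, both of this immunoprecipitation and described in its design text as biological replicates. An input, a control antibody or an uninjected embryo sample was not analysed here, so every value below is a level in the immunoprecipitate and not an enrichment over background.

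The processed table gives 1 RPKM value per gene (reads per kilobase of gene model, scaled to the library's read total), which the authors averaged over the replicates before deposit, as the name of the deposited table says. The table has no header. The submitters' processing notes name FastQC, cutadapt 1.13, Trimmomatic 0.36, TopHat2 2.1.1, Bowtie, MACS2 2.0.10 and bedtools 2.16.2, and the Zv9 genome build. The role of each tool, the annotation release, the gene lengths, the treatment of reads with several alignments and the use of strand are not given in the sources used here. Reads from a gene and its close copies, or from a gene and another gene inside it, therefore cannot be told apart. With replicates already averaged, no SD, test between replicates or leave-one-out value could be computed, and n is not repeated at each value.

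The table lists 33737 Ensembl gene identifiers. A table of gene names gave a symbol for 21939 of them (65.0%), comprising 19976 distinct symbols when letter case was ignored. Many symbols are in capitals, and 1342 symbols stand on several identifiers. The row with the symbol CPEB1 was taken as cpeb1b, because cpeb1a has a row of its own and the RefSeq gene table (assembly GRCz12tu) gives cpeb1 as a synonym of cpeb1b. The 2 rows named SHH were not assigned to shha or shhb. Genomic positions and sequences in Zv9 were not used here.

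Sequencing depth was read from the table itself. In an RPKM table made from whole reads, a gene with 1 read takes a value of a fixed step divided by the gene's length. Values between 0.4 and 2 shared by at least 3 rows (171 rows, 32 values) were searched for steps that gave whole lengths within a tolerance of 0.002, and multiples of a step were reduced to the smallest that still fitted. A pair of steps was found, 76.0 and 76.3 RPKM × nt, which accounted for 135 of the 171 rows (78.9%). If the deposited value is the plain mean of 2 libraries, they correspond to denominators of 6576775 and 6551358 reads, a difference of 0.388%. Which replicate has which depth cannot be read from the table. RPKM 1 then stands for about 13.1 reads per kilobase over both replicates, with a Poisson error of 27.6% for a 1 kb gene model. The corresponding error at RPKM 10 is 8.73%. These errors cover counting only, and reads without molecular identifiers are not independent molecules. On 2 simulated libraries of 5100000 and 5300000 reads the search returned both depths to within 7.4e-05%. The simulation itself took the plain mean of 2 libraries, so it does not test that assumption. Its depths also lie further apart than the 0.388% found here.

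Genes at RPKM 1 or more were called detected. Before the data were examined, 25 gene lists were fixed for the stage and the protein, 18 of them from symbols and 7 from naming patterns. Of 876 symbol entries 718 matched the names, either directly or after removal of a paralogue suffix. Pattern matches to the splicing-factor names that begin with U2 and to SNORC were removed from the small structural RNA list after it was inspected. For each list, the median RPKM of the detected members, with 1 row per symbol (the highest), was placed among the medians of 10000 random lists of the same size drawn from the 9786 detected symbols. The percentile describes these libraries, is not a p-value, and could not be matched on abundance because no other expression measurement was used. On simulated lists of 20 genes drawn from the 9786 detected symbols, the median exceeded 95% of random lists in 0 of 10 lists left unchanged, in 4 of 10 raised 1.5-fold, in 8 of 10 raised 2-fold and in 10 of 10 raised 4-fold. Genes were named by a rule fixed in advance, namely the Cpeb family, the 20 highest symbols, the 4 highest members of each list, and the Hedgehog ligands, receptors and Gli factors; of these entries dhh and gli1 had no matching symbol, and a gene that the rule names is not reported here. A further 14 gene families were chosen after the file had been opened.

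Alternatives changed the detection threshold to RPKM 0.1 or 5 or removed it, kept every row of a symbol, left out the highest genes, and changed the set in which cpeb1b was ranked. The planned comparison of replicates, the motif analysis of 3′ untranslated regions and the matching on transcript length were not run, because they need values per replicate, sequences and transcript lengths. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.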

Results

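RNA recovered by immunoprecipitation of Flag-tagged Cpeb1b was sequenced from zebrafish embryos at 16 hpf in 2 replicates, which the deposited table gives as 1 mean RPKM per gene. Cpeb1b belongs to the cytoplasmic polyadenylation element-binding proteins, which bind the 3′ untranslated regions of mRNAs and control their poly(A) tail length and translation. The series has a single group, so the question the data can answer is which transcripts were present in the immunoprecipitate and at what level. Of 33737 genes, 13021 (38.6%) had an RPKM of 1 or more, 2302 reached 10 and 269 reached 100, while 7930 were listed at 0. The median over all genes was 0.507 RPKM, and the median over the 9786 detected symbols was 3.22 RPKM. If the deposited value is the plain mean of 2 libraries, its steps correspond to RPKM denominators of 6576775 and 6551358 reads, and a value of 1 would stand for about 13.1 reads per kilobase in both libraries together.

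Genes without a symbol, whose identity is not known here, made up 65.8% of the RPKM total, and the fixed list of small structural RNAs, which does not hold rn7sl1, made up 18.7%. A single row of the 5.8S ribosomal RNA held 17.8% of the total, and the other rows of that list together held 0.815%. The 5.8S ribosomal RNA reached 182928 RPKM, the 7SK RNA (rn7sk), which regulates transcription elongation, 1813 RPKM, the Vault RNA 1184 RPKM, 5S ribosomal RNA 1036 RPKM, the signal recognition particle RNA rn7sl1 698 RPKM and the U5 spliceosomal RNA 575 RPKM. The 10 highest genes held 79.8% of the summed RPKM and the 100 highest held 88.5%. Of these, 7 and 47, respectively, had no symbol. The highest, ENSDARG00000070212, was listed at 342255 RPKM, 33.4% of the total, and ENSDARG00000080337 at 70649 RPKM, 6.89%. These are shares of summed RPKM, in which short genes weigh more than their reads. Of 55 small structural RNA symbols 40 were detected, with a median of 65.0 RPKM. Of 215 microRNA genes 52 were detected, with a median of 3.64 RPKM, above 74.5% of random lists. The median over all 215 was 0. The highest microRNA genes were MIRLET7F1 at 82.8 RPKM, mir130b at 61.7 RPKM, mir19c at 29.0 RPKM and dre-mir-133c at 25.9 RPKM. Values of 0.4 to 2 RPKM that fitted 1 read at the 76.0 step gave gene lengths of 54 to 180 nt. If microRNA gene models are that short, detection at RPKM 1 can rest on 1 or a few reads. The random lists were not matched on length.

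Among the family of the bait, the cpeb1b transcript stood above the other detected members. The row named CPEB1 (ENSDARG00000008454) had 30.5 RPKM, rank 783 of 33737 genes, above 97.7% of them. CPEB3 had 2.55 RPKM, CPEB2 2.41 RPKM and CPEB4 1.66 RPKM, so the cpeb1b value was 11.9, 12.6 and 18.3 times theirs, and cpeb1a was listed at 0. Genes that every cell uses, such as EIF3H and MRPS22, were also listed at 0, so a 0 does not show a low level. The median of the 4 detected members was 2.48 RPKM, above 25.5% of random lists, or 82.9% without the filter on low values. At the estimated depth, cpeb1b had about 400 reads per kilobase over both libraries, and CPEB4 about 21.8. The embryos had been injected with Flag-cpeb1b mRNA, and reads from that mRNA and from the endogenous gene are not separated in the table.

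Hedgehog pathway transcripts, which encode the signal from notochord and floor plate that patterns neighbouring tissues, were recovered at ordinary levels for detected genes. Of 20 measured members 16 were detected, with a median of 3.33 RPKM, above 52.8% of random lists. Of 2 ligand genes with the symbol SHH, ENSDARG00000068567 had 3.47 RPKM (about 45.5 reads per kilobase) and ENSDARG00000038867 had 0.302 RPKM (about 3.96 reads per kilobase), while ihha had 0.999 RPKM and ihhb 0.725 RPKM. The signal transducer SMO had 9.39 RPKM and the receptor PTCH1 2.49 RPKM. The transcription factor genes named GLI2 had 6.66 and 3.003 RPKM, and GLI3 had 2.22 RPKM. HHATL at 21.0 RPKM and the co-receptor BOC at 9.67 RPKM were also among the 4 highest of the list. With undetected genes left in both the list and the background, the list's median lay above 97.4% of random lists, and with a threshold of RPKM 5 above 44.0%.

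**Figure D1:**
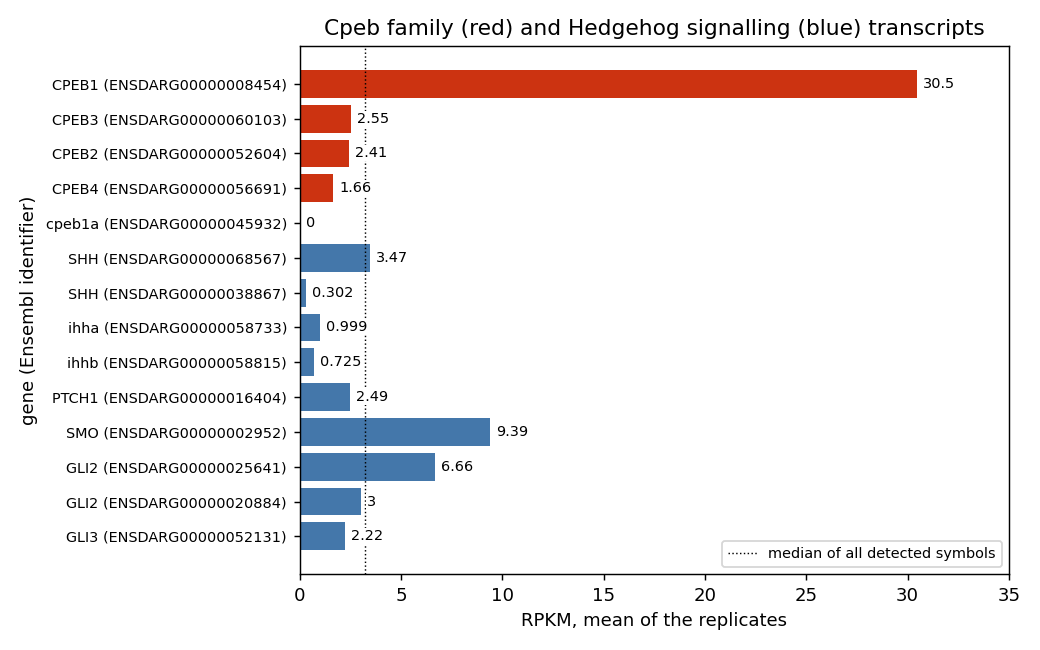
RPKM (mean of the replicates, horizontal axis, linear from 0) of each measured Cpeb family gene (red bars) and of the Hedgehog ligand, receptor and Gli genes reported here (blue bars), with the median of all detected symbols as a dotted line. The CPEB1 bar reaches 30.5, and the higher of the SHH bars, at 3.47, lies close to the dotted line at 3.22; no error bars are drawn because the table holds 1 mean per gene.

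Of 23 measured members of the cytoplasmic polyadenylation machinery list 18 were detected, with a median of 6.90 RPKM, above 98.8% of random lists. The list had 29 entries, and papd4 and tent2 were among those that matched no symbol, so they were not assessed. The poly(A)-binding protein gene pabpc1a had 444 RPKM, the nuclear poly(A)-binding protein gene PABPN1 35.1 RPKM, the cap-binding factor EIF4E 24.96 RPKM and the cleavage factor CPSF6 21.99 RPKM; these are general factors of mRNA processing and translation. The 5 members under RPKM 1 included the germline forms EIF4E1B at 0.569 RPKM and PABPC1L at 0.190 RPKM and the oocyte gene ZAR1L at 0.0696 RPKM. ZAR1, in the same list, had 4.15 RPKM, above the median of 3.22 RPKM for all detected symbols. EIF4E1B, PABPC1L, ZAR1L and ZAR1 were picked out after the values were seen. With a threshold of RPKM 5 the median of the list lay above 37.8% of random lists, and without its 4 highest members, a removal that can only lower the median, above 94.3%. All 27 measured deadenylation and decapping genes were detected, with a median of 4.00 RPKM, above 80.1% of random lists. The antiproliferative genes BTG1 and TOB1, whose products recruit deadenylases, had 49.7 and 17.4 RPKM, and the deadenylase subunit genes CNOT6 and cnot3b had 17.1 and 15.0 RPKM. Without the filter on low values, that list lay above 99.97% of random lists, and at RPKM 5 above 57.6%.

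Cell cycle transcripts stood high. Of 47 measured genes 44 were detected, with a median of 8.67 RPKM against 3.22 for all detected symbols, above all 10000 random lists. The spindle assembly factor TPX2 had 77.4 RPKM, the replication clamp PCNA 43.6 RPKM, the proliferation marker mki67 35.4 RPKM and the replicative helicase subunit MCM6 34.6 RPKM. CCNB1 and MOS, whose mRNAs are textbook CPEB targets in the frog oocyte, had 8.51 and 1.51 RPKM; both were picked out after the values were seen. With a threshold of RPKM 5 the cell cycle list lay above 86.7% of random lists. Of 36 germ plasm and maternal genes 20 were detected, with a median of 4.16 RPKM, above 79.6% of random lists at RPKM 1 and 98.4% at RPKM 5. Its highest members, YBX1 (329 RPKM), MYCN (90.7 RPKM), igf2bp1 (65.8 RPKM) and IGF2BP3 (36.8 RPKM), encode 3 RNA-binding proteins and a growth-promoting transcription factor and are not restricted to germ cells. Chosen after the values were seen, the germ cell genes DDX4, NANOS3 and DAZL had 1.46, 0.540 and 0.253 RPKM. RNA-binding and m6A protein genes had a median of 9.20 RPKM over 41 of 44 detected members, above all random lists and above 93.4% of them at RPKM 5. Besides YBX1, their highest were khdrbs1a at 304 RPKM, HNRNPAB at 200.4 RPKM and nucleolin (ncl) at 189.8 RPKM.

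Tissue lists differed in level. The list of epidermis, hatching gland and yolk syncytial layer had 41 of 47 members detected and a median of 11.6 RPKM, above all random lists. Its highest members were the keratin genes krt4 (319 RPKM) and krt5 (198 RPKM) and the apolipoprotein genes apoc1 (278 RPKM) and apoa1a (263 RPKM). In contrast, the endothelial list had 15 of 26 members detected and a median of 2.25 RPKM. That median lay above 11.5% of random lists at RPKM 1 and 60.1% without the filter on low values. Its highest members were CLDN5 at 58.0 RPKM, EFNB2 at 15.2 RPKM, etsrp at 4.56 RPKM and flt1 at 3.46 RPKM. The list entries cldn5b and efnb2a were matched to CLDN5 and EFNB2 without their paralogue suffix, so these rows may be other paralogues. Blood and hematopoietic stem cell genes had 19 of 36 detected and a median of 3.12 RPKM, above 45.9% of random lists, led by znfl2a at 20.5 RPKM, CEBPA at 11.7 RPKM, GATA2 at 5.72 RPKM and MYB at 5.21 RPKM. RUNX1, the regulator of definitive hematopoiesis, had 0.549 RPKM, a value looked up afterwards.

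Notochord and floor plate genes had 22 of 30 detected with a median of 4.89 RPKM, above 92.0% of random lists. The laminin gene lamc1 had 18.4 RPKM, the cartilage and notochord collagen COL2A1 15.8 RPKM, the notochord transcription factor noto 13.7 RPKM and ckap4 9.71 RPKM. Somite and muscle genes had 37 of 53 detected and a median of 4.12 RPKM, above 86.4% of random lists. The muscle chaperone hsp90aa1.1 had 33.5 RPKM, cardiac actin actc1a 33.3 RPKM, the tropomyosin tpm3 28.5 RPKM and the somite factor MEOX1 18.9 RPKM. Neural genes had 47 of 55 detected and a median of 3.71 RPKM, above 76.7% of random lists. The tubulin regulator STMN1 had 33.0 RPKM, sox19a 30.3 RPKM, SOX3 21.2 RPKM and NEUROD4 18.7 RPKM. Without the filter on low values, these lists lay above 99.7%, 99.9% and 100% of random lists, respectively, and at RPKM 5 above 27.9%, 83.4% and 85.9%.

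Notch pathway genes had 27 of 34 detected and a median of 3.62 RPKM, above 67.5% of random lists, with her2 at 16.5 RPKM, adam10a at 10.1 RPKM, NOTCH3 at 8.32 RPKM and the segmentation clock gene her7 at 5.99 RPKM. BMP and Wnt pathway genes had 40 of 51 detected and a median of 4.30 RPKM, above 90.4% of random lists, with the Wnt receptor FZD7 at 17.8 RPKM, beta-catenin (CTNNB1) at 16.4 RPKM, the BMP-responsive ID1 at 16.0 RPKM and GSK3B at 14.4 RPKM. Without the filter on low values they lay above 99.7% and 100% of random lists, and at RPKM 5 above 11.6% and 57.4%.

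**Figure D2:**
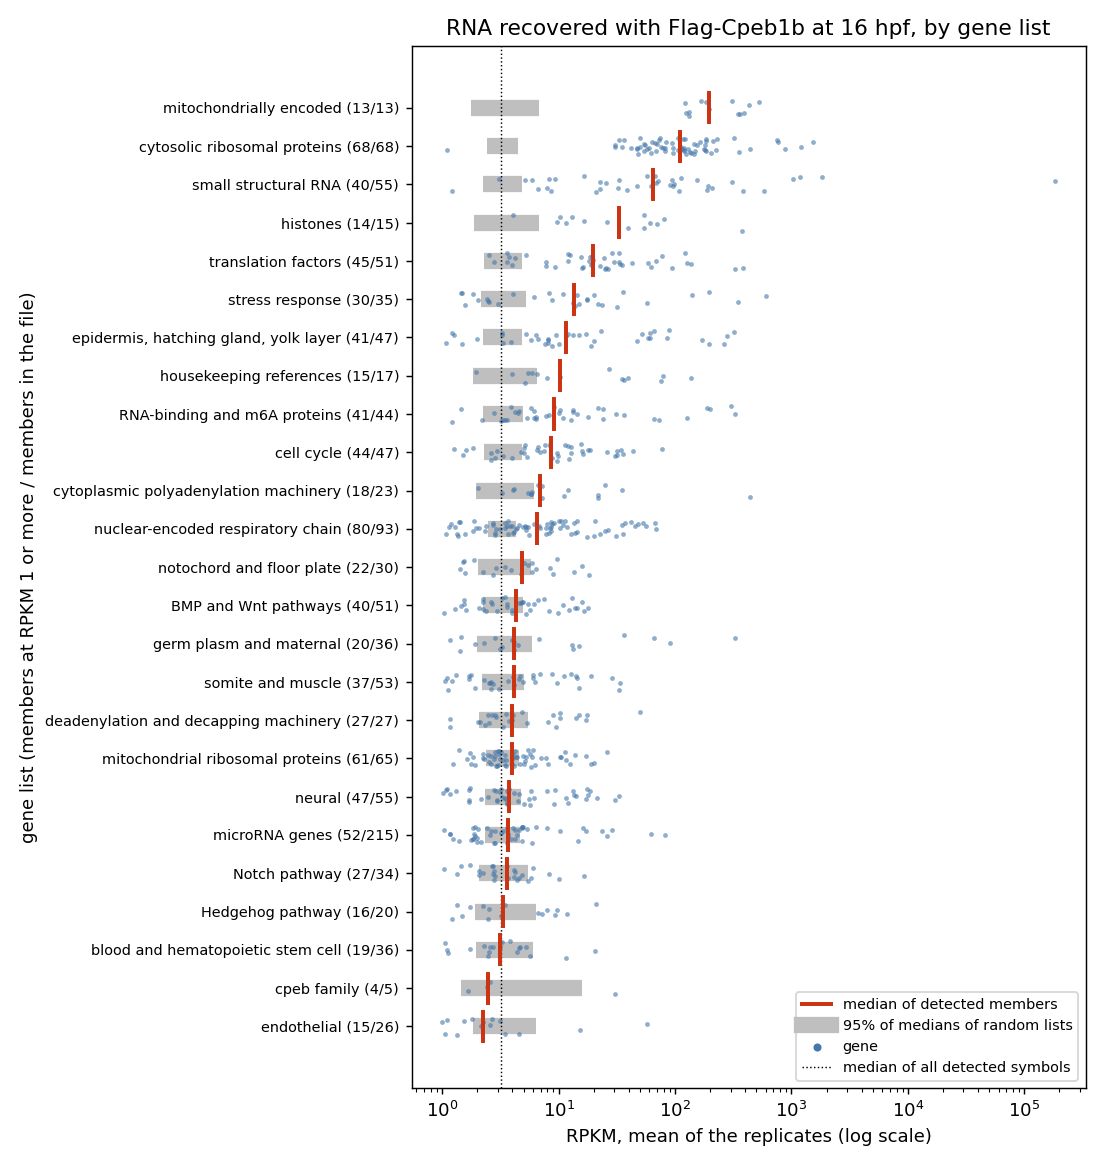
RPKM (mean of the replicates, horizontal log axis) of the detected members of each fixed gene list (points), their median (red bar) and the range holding 95% of the medians of 10000 random lists of the same size (grey). Medians run from 2.25 for endothelial genes to 194 for mitochondrially encoded genes, and numbers in brackets give detected members and members in the table.

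Mitochondrially encoded, cytosolic ribosomal protein and translation factor genes had medians well above that of all detected symbols. All 68 measured cytosolic ribosomal protein genes were detected, with a median of 110 RPKM, led by RPS14 at 1535 RPKM, RPL21 at 1203 RPKM, RPL35 at 874 RPKM and rplp2l at 761 RPKM, and RPL6 had 758 RPKM. Together they made up 1.23% of the RPKM total. The mitochondrially encoded list holds 13 genes, all of them protein-coding, and no mitochondrial rRNA or tRNA. All 13 were detected, with a median of 194 RPKM, led by MT-ND6 at 530 RPKM, MT-CO2 at 434 RPKM, MT-ATP6 at 388 RPKM and MT-CO1 at 363 RPKM. These transcripts are made and kept inside mitochondria, and no control precipitate was used here to set a background for them. Translation factors had 45 of 51 detected and a median of 19.7 RPKM, led by eef1a1l1 at 383 RPKM, EIF2S2 at 330 RPKM, EEF1G at 137 RPKM and TPT1 at 126 RPKM. Nuclear-encoded respiratory chain genes had 80 of 93 detected and a median of 6.50 RPKM, with COX4I1 at 68.7 RPKM, NDUFA6 at 67.2 RPKM, atp5if1a at 56.1 RPKM and NDUFS5 at 52.6 RPKM. At RPKM 5 this last list lay above 85.7% of random lists. Mitochondrial ribosomal protein genes had 61 of 65 detected and a median of 4.00 RPKM, above 89.2% of random lists at RPKM 1, above all of them without the filter on low values and above 10.3% of them at RPKM 5. Its highest members were mrpl52 at 26.0 RPKM, mrps31 at 20.1 RPKM, mrpl54 at 18.9 RPKM and mrpl30 at 17.1 RPKM.

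Stress-response genes had 30 of 35 detected and a median of 13.6 RPKM, above all random lists. The highest were the chaperones HSP90AB1 at 602 RPKM, HSPA8 at 344 RPKM, HSPB1 at 195 RPKM and SERPINH1 at 139 RPKM. The 5 members under RPKM 1, looked up afterwards, were egr1 (0.965), bbc3 (0.840), hsp70.1 (0.670), JUNB (0.587) and hsp70l (0.430). Histone genes had 14 of 15 detected and a median of 32.9 RPKM, led by hist1h2a3 at 374 RPKM, h3f3d at 81.0 RPKM, hist1h2a11 at 69.4 RPKM and hist2h3c at 61.5 RPKM; near-identical histone copies make single values uncertain. Reference genes had 15 of 17 detected and a median of 10.4 RPKM, above 99.9% of random lists, with actb2 at 137 RPKM, actb1 at 79.0 RPKM, ppiaa at 75.4 RPKM and tuba8l4 at 39.7 RPKM.

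Several of the 20 highest symbols belonged to no fixed list. They were si:dkey-153m14.1 at 46160 RPKM, AJUBA, which encodes a LIM-domain scaffold protein, at 8181 RPKM, si:dkey-151g10.6 at 1463 RPKM, si:ch211-222l21.1 at 796 RPKM, the chromatin protein gene hmga1a at 773 RPKM, rn7sl1 at 698 RPKM, JAKMIP2 at 580 RPKM and si:dkeyp-104f11.4 at 525 RPKM.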

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

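The number of detected genes followed the threshold, with 23844 at RPKM 0.1 and 4490 at RPKM 5 against 13021 at RPKM 1. The number of lists above 95% of random lists was 12 at RPKM 1 and 20 without the filter on low values, a setting in which genes under RPKM 1 enter the lists and the background; it was 9 at RPKM 5, 12 with every row of a symbol kept and 11 without the 4 highest members of each list, the last chosen after seeing the data and able only to lower a median. Of the 25 lists, 8 lay above 95% under each of these settings (ribosomal, mitochondrially encoded, small structural RNA, histone, translation factor, stress, reference, and epidermis with yolk layer), blood and microRNA genes lay at or below it under each, the Cpeb family and endothelial lists lay at or below it under those settings that left at least 3 members, which excludes RPKM 5 for both and the removal of the 4 highest for the Cpeb family, and 13 changed side. Without the single highest gene the 10 highest held 70.7% and the 100 highest 82.7% of the RPKM total, against 79.8% and 88.5%. Without the listed mitochondrially encoded genes and small structural RNAs they held 77.3% and 86.6%, and without cpeb1b 79.8% and 88.5%. The rank of cpeb1b was 783 among all genes, 514 among those with a symbol and, in a setting chosen after seeing the data, 376 among symbols matched to a protein-coding RefSeq gene, where 97.3% lay below it. No paired analysis was possible because the series has 1 group, and none without a replicate because the table holds only the mean. Depth limits single genes near RPKM 1, where a 1 kb gene model has about 13.1 reads and a shorter one has fewer.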

Other observations

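The gene families below were chosen after the file had been opened, and the test of the share of nested small RNA genes among the 100 highest was chosen after its count was seen. Families of general cell function were recovered at high levels. Of 49 proteasome subunit genes 41 were detected, with a median of 13.1 RPKM over the detected members, led by PSME1 at 111 RPKM and PSMD5 at 51.8 RPKM. All 8 chaperonin subunit genes were detected with a median of 18.4 RPKM, led by CCT3 at 30.4 RPKM. Splicing factor genes had 33 of 35 detected and a median of 16.8 RPKM, led by SF3B2 at 43.6 RPKM. Tubulin genes had 13 of 19 detected and a median of 15.2 RPKM, led by tubb4b at 102 RPKM. Hox genes, the positional regulators of the body axis, had 34 of 37 detected and a median of 5.41 RPKM, above 98.6% of random lists, with HOXC8 at 43.8 RPKM, hoxb6b at 27.9 RPKM and HOXC6 at 19.0 RPKM.

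Collagens and cadherins stood lower over their detected members. On that measure crystallins (3.06 RPKM) and odorant receptors (2.67 RPKM), with few detected members, were no lower than collagens. Over all members, collagens had a median of 1.33 RPKM and cadherins and protocadherins 0.570 RPKM. Families of later tissues had all-member medians below the 0.507 RPKM of all genes. Collagens had 29 of 46 detected, with a median of 2.66 RPKM, above 20.7% of random lists, and cadherins and protocadherins had 17 of 45 detected, with a median of 2.67 RPKM, above 26.7%. Claudins had 15 of 31 detected and a median of 3.23 RPKM, above 50.8%, and kinesins had 22 of 35 and a median of 4.57 RPKM, above 88.1%. Of 168 odorant receptor genes 4 reached RPKM 1 and 70 were listed at 0, with a median of 0.0587 RPKM over all members. Only 4 of 48 crystallin genes (median over all members 0.0894 RPKM), 1 of 20 opsin genes (0.170 RPKM), 1 of 31 pancreatic digestive enzyme genes (0.214 RPKM) and 0 of 8 vitellogenin genes (0.0478 RPKM) reached it. These medians give a level for genes mostly used by tissues that differentiate later, in a series with no control precipitate, and the higher SHH row, at 3.47 RPKM, lay above each of them while the lower, at 0.302 RPKM, lay close to the upper ones.

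Several protein-coding genes outside the lists stood high, such as AJUBA at 8181 RPKM, JAKMIP2 at 580 RPKM, CYB5D2 at 444 RPKM and the tendon factor scxb at 304 RPKM; the last 2 fall outside the naming rule and were chosen after their values were seen. A candidate explanation is that reads of a small RNA gene inside the gene were counted to it. In the RefSeq gene table (assembly GRCz12tu, not the build of the reads), 0 of the 100 highest such genes overlapped an rRNA, tRNA or snRNA gene. Only 25 of all 6822 detected genes examined overlapped one, and random sets matched on gene span had a median of 0. The comparison with random sets therefore cannot decide. Within that assembly, no annotated gene of these classes was there as a source for the 100. Zv9 gene models were not searched, so genes placed differently there stay open. For snoRNA and microRNA genes the count was 4 of 100 (DKC1, NOP56, ranbp1 and rsl1d1), above 99.9% of 10000 random sets matched on gene span. The explanation predicts such an excess for those 4, but hosts of such RNAs may also be abundant themselves. The exact 95% upper bound of that share was 9.93%, but it treats the 100 highest genes as a random sample, which they are not. The bound therefore cannot decide for most of the 100. Within that assembly, only those 4 overlapped an annotated gene of these classes, and Zv9 gene models were not searched. Unannotated repeats, reads with several alignments and true abundance stay open, and no biological explanation was tested.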
